A study of Mus musculus with 14 samples.

How the data were processed

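Gene expression was measured on 14 Illumina mouse beadchip arrays hybridised with biotin-labelled cRNA, per the labels' protocols. The arrays fall into 7 groups of 2, taken from the sample titles and descriptions. A double-reporter embryonic stem cell (ESC) line carried GFP driven by the distal enhancer of Oct4 (the gene Pou5f1) and RFP driven by its proximal enhancer. It gave 4 groups sorted on these reporters: serum plus LIF, GFP-positive and RFP-positive; serum plus LIF, GFP-positive and RFP-negative; N2B27 medium with LIF and 2 inhibitors (2i: 3 µM CHIR99021 and 1 µM PD0325901), GFP-positive and RFP-negative; and epiblast-like cells (EpiLCs), GFP-negative and RFP-positive. The other groups were epiblast stem cells (EpiSCs), mouse embryonic fibroblasts (MEFs) and an ESC line in serum plus LIF that carried only the distal-enhancer GFP reporter, with no sort gate given in the labels. The labels number the replicates 1 and 2 within each group, and nothing in them says that replicates came from separate cultures. All p-values therefore measure only the spread between these arrays, which may be technical.

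The deposited scanner table holds, per the file headers, a non-normalized signal intensity for each of 25697 probes on each array. It also holds a detection p-value per probe and array, per the file headers, which is low where a probe lies above the negative controls. The submitters' processing notes name GenomeStudio 2011.1; how it was set to average beads and treat background is not given in the sources used here. Array medians of the scanner signal were 142.6 to 209.4 on 12 arrays, and 313.5 and 316.8 on the EpiSC arrays. A detection p-value under 0.05 was reached by 11916 to 13815 probes per array (46.4% to 53.8%). The authors also deposited a table of processed values on a log2 scale, and its method is not given in the sources used here. It was matched by quantile normalizing the log2 scanner signals without background correction: 100% of its values lay within 0.01 log2 of that rebuilt table, with a largest difference of 0.00302. Each of its 14 columns had a median of 7.53, with no centring of genes, and it served as an alternative. No array column was left unassigned to a sample.

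Background correction and normalization used neqc in limma 3.58.1 under R 4.3.3: normexp with the negative-control mean and variance inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes were named through the platform's probe annotation, updated through a current gene table: 23978 probes had 1 symbol, 0 had several and 1719 had none. Of the named probes, 23962 matched the current table and 16 kept the annotation's own symbol, which gave 16593 symbols. Genes can carry several probes. Each was represented by its probe with the highest mean over all arrays among probes with a detection p-value under 0.05 on both arrays of at least 1 group, which left 10481 genes to test.

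All 14 arrays entered 1 limma model of group means (lmFit, eBayes), since a group of 2 arrays says little about spread by itself. The residual degrees of freedom were 7, the prior added 2.5, and each gene's spread was thus mainly estimated over the other groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each of 8 comparisons, and every adjusted p of a gene is from this limma model. The number of arrays limits the precision: a gene's 95% interval for the difference of a pair of groups had a median half-width of 0.29 log2. A gene whose probes were not detected on any array of the dimmer side has only a bound there. It is given as "at least N-fold": the brighter side's mean against, per array, the higher of the gene's own signal and the lowest signal among detected probes. No fold is given where both sides lay below background. No probe's level is set against that of another probe.

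The 25 gene lists were core pluripotency, naive pluripotency, post-implantation epiblast, primitive streak and mesendoderm, extraembryonic endoderm, neural, trophoblast, fibroblast and feeder, germline, two-cell-like, DNA methylation machinery, ERK pathway targets, Wnt and beta-catenin targets, LIF and STAT3 targets, BMP targets, Nodal and activin targets, epithelial, mesenchymal regulators, glycolysis, oxidative phosphorylation, cholesterol synthesis, proliferation, stress and immediate early, imprinted, and sex-linked genes. Of their 317 members (some in several lists), 238 were tested. The 24 lists with more than 1 tested member were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists within each comparison, and again with a correlation estimated from the arrays. Members were also called with adjustment over the list alone; where no other count is given, that count was the same. The groups, comparisons, lists, tests and alternatives set in advance, and the rule for naming genes, were set before the data were examined. The rule allows, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes that were detected on every array of the higher side and had no overlap between sides; the 4 members of each list with the largest change; and Pou5f1, Sox2 and Nanog. Genes named outside it are said to have been chosen after their values were seen.

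The steps were tested on simulated data for the comparison of the serum gates, with 200 of 10481 genes changed in each of 10 simulations. The model called 41% of changes of 0.5 log2, 80.1% of changes of 1 log2 and 98.3% of changes of 2 log2 in the right direction. Of its calls, 5.44% were false, and the median error of the log2 change was −0.003. Lists of 12 rising genes, mixing changes of 0.5, 1 and 2 log2, had a camera p under 0.05 in 10 of the 10 simulations. This held with the preset and with the estimated correlation. Lists of 12 unchanged genes had one in 0, with the preset correlation. These p-values were not adjusted over lists, and noise was drawn independently for each gene. The simulations therefore cannot show how often lists of correlated genes are called.

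The alternatives set in advance were no background correction, median scaling, the authors' processed values, no detection filter, a detection p-value under 0.01, all probes, only the groups compared, no MEF arrays, an intensity trend with robust eBayes, at least 2-fold, the replicate number as a block, each array left out, an estimated correlation, and EpiSC-derived sets in place of EpiLC-derived ones. Others were added after seeing the data and are named as such with their values. A chip block was not run, because the column names give no chips. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.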

Results

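Gene expression was compared between sorted mouse ESCs in serum or 2i, EpiLCs, EpiSCs, a single-reporter ESC line and MEFs, with 2 arrays per group and 14 arrays in all. The ESCs and EpiLCs of the double-reporter line were sorted on a GFP reporter of the distal enhancer and an RFP reporter of the proximal enhancer of Oct4. Values are log2 signals of 10481 genes, given as log2 changes with their standard error (SE) or as group means with the standard deviation of 2 arrays. With 2 arrays per group, a gene's 95% interval had a median half-width of 0.29 log2, so smaller changes were seldom called. Nothing in the labels says that the replicates came from separate cultures.

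Pou5f1 itself varied little among the pluripotent groups, from 13.06 ± 0.08 in EpiLCs to 13.77 ± 0.03 in RFP-positive serum cells, and lay below background in MEFs. Nanog stayed between 12.74 ± 0.16 (single-reporter ESCs) and 14.06 ± 0.03 (EpiSCs), while Sox2 fell from 9.99 ± 0.15 in 2i to 6.68 ± 0.10 in EpiLCs and 6.11 ± 0.28 in EpiSCs. Esrrb, a naive transcription factor, was at 15.27 ± 0.05 in 2i, 9.34 ± 0.15 in EpiLCs and 9.73 ± 2.24 in EpiSCs, where the 2 arrays lay far apart. Correlations across genes, which are not independent replicates, were 0.997 to 0.998 between replicates of the other groups and 0.976 between the EpiSC arrays. Across genes, the group means of both serum gates correlated at 0.998, those of RFP-negative serum cells and 2i cells at 0.967, of EpiLCs and 2i cells at 0.918, and of EpiSCs and 2i cells at 0.895.

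**Figure D1:**
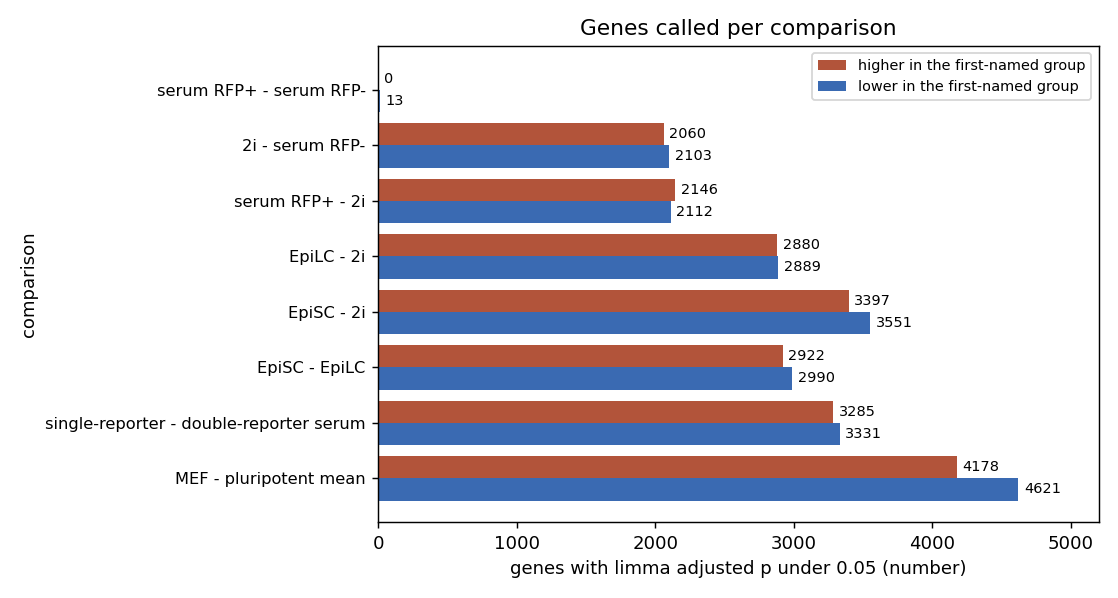
Number of genes called higher and lower (adjusted p under 0.05) in each of the 8 comparisons of 10481 genes. The serum gates differed in 13 genes and MEFs from the pluripotent groups in 8799.

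**Figure D2:**
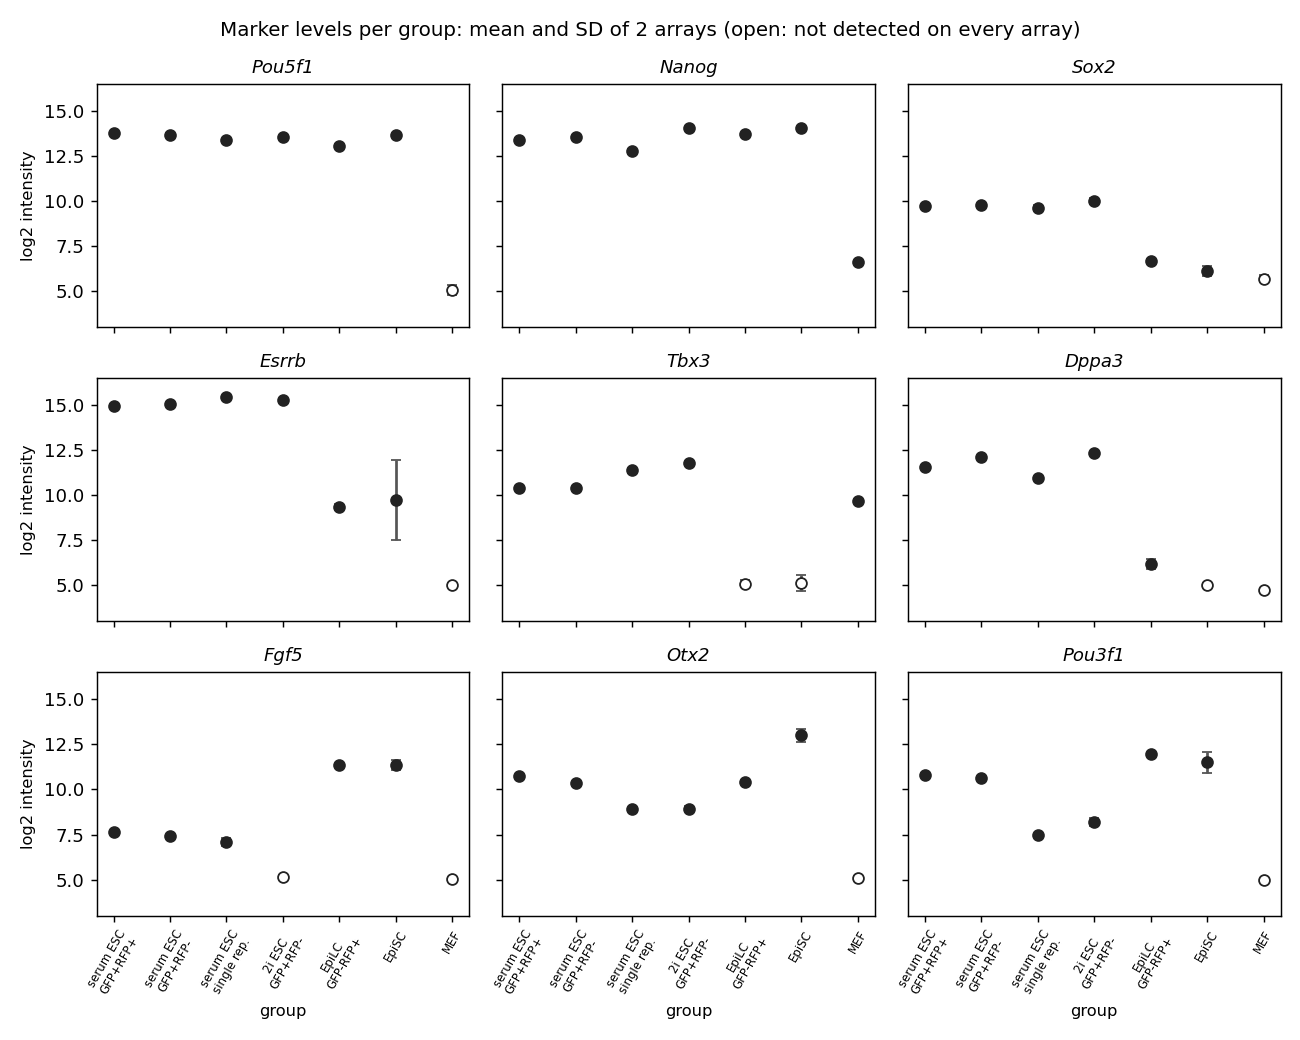
Levels (log2 signal, mean and standard deviation of 2 arrays) of Pou5f1, Nanog, Sox2, naive genes and post-implantation genes in the 7 groups. Open points mark groups where the gene was not detected on every array. Dppa3 was at 12.34 in 2i and 6.18 in EpiLCs, and Pou5f1 at 13.54 and 13.06.

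In serum, the RFP-positive and RFP-negative gates differed in few genes, all of them lower in RFP-positive cells (n = 2 per gate). The X-linked homeobox genes Rhox6 and Rhox9 fell by 1.39 log2 (SE 0.15) and 1.25 log2 (SE 0.08), from 8.34 to 6.95 and from 10.04 to 8.79. The Wnt ligand gene Wnt7b fell by 1.32 log2 (SE 0.14), the iron exporter gene Slc40a1 by 0.90 log2 (SE 0.09) and the germ cell gene Nanos3 by 0.74 log2 (SE 0.08), with adjusted p of 0.0084 or lower for these 5 genes. Lower levels were also called for the keratin gene Krt23 (0.86 log2, SE 0.08, adjusted p 0.006), the transcription cofactor gene Zfpm1 (0.83 log2, SE 0.10, adjusted p 0.013), the actin-bundling gene Espn (0.76 log2, SE 0.09, adjusted p 0.013) and AA467197 (0.85 log2, SE 0.12, adjusted p 0.041). The retinol dehydrogenase gene Adh7 was at least 1.53-fold lower, since it was not detected in RFP-positive cells. The trophoblast and germ cell factor gene Tfap2c fell by 0.62 log2 (SE 0.09, adjusted p 0.041), from 13.59 to 12.97. Only Rhox9 stayed called whichever array was left out. Leaving out RFP-negative array 1 ended the other calls named here, RFP-positive array 1 all of these but Rhox6, RFP-positive array 2 all but Adh7, and RFP-negative array 2 all but Rhox6, Krt23 and Adh7. The calls of AA467197 and Tfap2c also ended without any array of the 2i, EpiLC, MEF or single-reporter groups, with the replicate block, with all probes and without the detection filter. The call of Nanos3 ended with an intensity trend and robust eBayes, and that of Adh7 without background correction. With only the serum arrays in the fit none was called.

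Pluripotency genes were not called between the serum gates: Pou5f1 was at 13.77 ± 0.03 and 13.64 ± 0.12 (difference 0.13 log2, 95% interval −0.15 to 0.40). Sox2 (−0.02 log2, SE 0.15), Nanog (−0.17 log2, SE 0.09) and Dppa3 (−0.58 log2, SE 0.11, adjusted p 0.23) were not called either, although Dppa3 was called without background correction (−0.56 log2, adjusted p 0.0031) or with either EpiLC array left out. Nor were the post-implantation genes Otx2 (0.36 log2, SE 0.15, adjusted p 0.85) and Lef1 (0.56 log2, SE 0.20, adjusted p 0.69) called. Of the list members, 0 of 10 core pluripotency, 0 of 12 naive and 0 of 12 post-implantation genes were called, against 1 of 7 trophoblast genes (Tfap2c). Adjusted over the list alone, 2 naive genes were lower.

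By limma, 13 genes were called between the serum gates, 0 higher and 13 lower, against 578 with an unadjusted p under 0.05 (223 higher and 355 lower). Of all genes, 98.7% differed by less than 0.5 log2. Leaving out a serum array left 1 to 4 of these calls, while leaving out either EpiSC array gave 45, so the count is set mainly by the spread assumed. None of the 24 lists was called; the lowest list p, adjusted 0.19, was shared by the naive, post-implantation, trophoblast and epithelial lists. The naive list had a median of −0.08 log2 and the post-implantation list one of 0.18 log2. List medians of Nodal targets (0.03, and 0.00 with median scaling) and glycolysis genes (−0.01, and 0.03 with median scaling) were near 0 on any scaling. Median and mean differed in sign for neural (0.01 and −0.11), germline (0.08 and −0.04) and extraembryonic endoderm genes (−0.01 and 0.01).

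The gene sets that set EpiLCs apart from 2i cells, a comparison that shares no arrays with the serum gates, were not called between the gates. The 1225 genes at least 2-fold higher in EpiLCs had a median of −0.03 log2 between the gates (camera p 0.12, and 0.35 with an estimated correlation), with 43.2% of them higher in RFP-positive cells. The 939 genes at least 2-fold lower in EpiLCs had a median of −0.003 log2 (camera p 0.30). Across genes, which are not independent, both changes correlated at −0.03. Of the 13 genes called between the gates, however, 7 were also lower in EpiLCs than in 2i cells, among them Rhox9, Rhox6 and Tfap2c. Another 3 were higher and 3 were not called, a count made after the genes were seen. Of all 10481 genes, 2889 were lower and 2880 higher in EpiLCs than in 2i cells.

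2i cells, against serum cells of the same RFP-negative gate, had higher levels of naive genes and lower levels of post-implantation genes and ERK targets (n = 2 per group). Among naive genes, Prdm14, a repressor of differentiation, rose by 1.65 log2 (SE 0.12, detected on 1 of 2 serum arrays), Tcl1 by 1.59 log2 (SE 0.44), Tbx3 by 1.42 log2 (SE 0.18) and Fbxo15 by 1.30 log2 (SE 0.24). The call of Tcl1 was lost without any of the RFP-negative serum or 2i arrays. Nanog rose by 0.50 log2 (SE 0.09), while Pou5f1 (−0.10 log2, SE 0.12, adjusted p 0.55) and Sox2 (0.24 log2, SE 0.15, adjusted p 0.26) were not called. The POU factor gene Pou3f1 fell by 2.45 log2 (SE 0.21), and Fgf5, Fgf15 and Wnt8a, genes of post-implantation ligands, were at least 2.94-fold, 2.31-fold and 1.91-fold lower and not detected in 2i. The ERK phosphatase gene Dusp4 fell by 4.18 log2 (SE 0.09), Etv4 by 2.47 log2 (SE 0.14) and Phlda1 by 2.12 log2 (SE 0.38), whereas the immediate early gene Fos rose by 2.39 log2 (SE 0.11). The naive list was called with 7 higher and 1 lower of 12 (adjusted p 0.02; adjusted p = 0.3 with an estimated correlation) and the post-implantation list with 1 higher and 7 lower of 12 (0.0096; adjusted p = 0.48 with an estimated correlation). ERK targets were called with 2 higher and 7 lower of 14, or 3 and 8 adjusted over the list alone (adjusted p 0.0093; adjusted p = 0.1 with an estimated correlation).

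The 3 metabolic lists were called higher in 2i with the preset correlation, but not with an estimated correlation, and not every member rose. Cholesterol synthesis genes rose in 9 of 11 with none lower (median 1.06 log2, adjusted p 5.3e-06; adjusted p = 0.15 with an estimated correlation), among them the sterol enzyme genes Msmo1 by 1.56 log2 (SE 0.10), Dhcr7 by 1.51 log2 (SE 0.08) and Fdps by 1.35 log2 (SE 0.07). Glycolysis genes were 8 higher and 1 lower of 13, or 9 and 1 adjusted over the list alone (adjusted p 0.0067; adjusted p = 0.1 with an estimated correlation), with the phosphofructokinase gene Pfkp up by 1.47 log2 (SE 0.18) and the glucose transporter gene Slc2a1 by 0.97 log2 (SE 0.10). Oxidative phosphorylation genes were 8 higher and 0 lower of 19 (adjusted p 0.0093; adjusted p = 0.48 with an estimated correlation), with the respiratory chain genes Cox7a2 up by 0.76 log2 (SE 0.09) and Sdhb by 0.75 log2 (SE 0.09). Imprinted genes fell in 9 of 12 with none higher (median −0.94 log2, adjusted p 5e-05; adjusted p = 0.1 with an estimated correlation): the growth regulator genes Grb10 by 2.34 log2 (SE 0.07) and Cdkn1c by 1.48 log2 (SE 0.14), and Peg10 by at least 5.13-fold.

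The largest rises in 2i were those of Spic, a myeloid transcription factor gene (4.33 log2, SE 0.10), the kinesin-binding gene Jakmip1 (3.16 log2, SE 0.16), the immediate early gene Ier2 (3.03 log2, SE 0.27, detected on 1 of 2 serum arrays) and the secreted Wnt antagonist gene Sfrp1 (2.85 log2, SE 0.10). The protease gene Klk1 was at least 8.28-fold and the transcription factor gene Mitf at least 4.36-fold higher. The largest falls were those of Slc40a1 (6.01 log2, SE 0.09) and of interferon-response genes, with Usp18 at least 57.9-fold lower, Ifit3 down by 4.49 log2 (SE 0.92) and Oasl2 by 4.28 log2 (SE 0.13). The epithelial factor gene Grhl2 was at least 21.7-fold lower. The proteases Mmp3 and Mmp10 and the chemokine gene Ccl2 were at least 23.9-fold, 19.3-fold and 11.9-fold lower, and the BMP antagonist gene Grem1 fell by 4.55 log2 (SE 0.68). Beside these, the fibroblast and feeder list had a mean level of 8.93 on the RFP-negative serum arrays and of 8.30 and 8.32 on the 2i arrays, with 2 members higher and 4 lower of 15 and no call as a list (adjusted p 0.52). Acta2 fell by 3.62 log2 (SE 1.14) and Twist2 by 3.22 log2 (SE 0.72, detected on 1 of the 2i arrays). The call of Acta2 was lost without any of the RFP-negative serum or 2i arrays, and with an intensity trend and robust eBayes.

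Other lists were not called in 2i. DNA methylation genes had 0 higher and 1 lower of 5, with the methyltransferase gene Dnmt3b down by 1.38 log2 (SE 0.06) and Dnmt3l not called (−2.31 log2, SE 0.90, adjusted p 0.067; called with either EpiSC array left out, with only the groups compared, without background correction and with the authors' values), so that the list's median (0.08) and mean (−0.65) differed in sign. Nodal targets had 2 higher and 1 lower of 6, with Lefty2, a Nodal antagonist gene, up by 2.14 log2 (SE 0.49), and Wnt targets 2 higher and 2 lower of 8, with Notum up by 2.12 log2 (SE 0.09). Stress genes had 5 higher and 4 lower of 11 (6 and 5 alone), with Ddit3 down by 2.24 log2 (SE 0.25), and epithelial genes 0 higher and 3 lower of 10, with the splicing factor gene Esrp1 down by 1.31 log2 (SE 0.13). BMP targets went both ways (2 higher and 3 lower of 7), with Id4 up by 1.77 log2 (SE 0.19) and Id1 down by 1.39 log2 (SE 0.25). Extraembryonic endoderm genes had 0 higher and 4 lower of 14 (Dab2 down by 3.36 log2, SE 0.20), neural genes 2 higher and 0 lower of 5 (Map2 up by 1.39 log2, SE 0.10), and mesenchymal regulators 0 higher and 3 lower of 7. Trophoblast genes had 1 higher and 3 lower of 7 (1 and 4 alone), LIF targets 3 and 3 of 9 (3 and 4 alone), proliferation genes 3 and 1 of 10 (6 and 1 alone), streak genes 2 and 2 of 9, germline genes 1 and 2 of 7 and sex-linked genes 0 and 1 of 4. The two-cell-like list had 1 tested member, which was not called. Core genes had 2 higher and 3 lower of 10, and the list median was −0.07 log2 but 0.07 with median scaling, as that of sex-linked genes moved from −0.01 to 0.06.

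In all, 4163 genes were called in 2i, 2060 higher and 2103 lower, with 396 and 671 at least 2-fold. All 7 list calls were lost with an estimated correlation.

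RFP-positive serum cells were also compared with 2i cells, and the same 7 lists were called, all of them lost with an estimated correlation (n = 2 per group, with the 2i arrays shared with the comparison above). Dusp4 rose by 3.91 log2 (SE 0.09), Pou3f1 by 2.62 log2 (SE 0.21), the head homeobox gene Otx2 by 1.80 log2 (SE 0.15) and Dnmt3b by 1.46 log2 (SE 0.06), and Fgf5 was at least 3.5-fold higher. Nanog fell by 0.67 log2 (SE 0.09, adjusted p 0.00036), Tcl1 by 1.80 log2 (SE 0.44) and Tbx3 by 1.40 log2 (SE 0.18), and Prdm14 was at least 2.91-fold lower. Pou5f1 (0.23 log2, SE 0.12, adjusted p 0.18) and Sox2 (−0.26 log2, SE 0.15, adjusted p 0.21) were not called, although Pou5f1 was with only the groups compared (adjusted p 0.046). Spic was at least 20.3-fold lower, and Slc40a1 was higher by 5.12 log2 (SE 0.09). Lists called were the naive (1 higher and 8 lower of 12, adjusted p 0.0068; adjusted p = 0.18 with an estimated correlation), post-implantation (7 and 1 of 12, 0.0037; adjusted p = 0.45 with an estimated correlation) and ERK lists (7 and 3 of 14, or 8 and 3 alone, 0.012; adjusted p = 0.14 with an estimated correlation). Imprinted genes (9 higher and 0 lower of 12, 0.00023; adjusted p = 0.14 with an estimated correlation) and cholesterol genes (0 and 9 of 11, 6.1e-06; adjusted p = 0.16 with an estimated correlation) were also called. So were glycolysis genes (1 higher and 7 lower of 13, or 1 and 8 alone, 0.0067; adjusted p = 0.14 with an estimated correlation) and oxidative phosphorylation genes (0 and 7 of 19, 0.0086; adjusted p = 0.48 with an estimated correlation). Of 4258 genes called, 2146 were higher and 2112 lower; with median scaling the split was 1793 higher and 2674 lower. The sex-linked median, −0.03 log2, was 0.01 without background correction.

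EpiLCs, against 2i cells, lost naive genes and gained post-implantation and epithelial genes (n = 2 per group). Dppa3, a maternal chromatin factor gene, fell by 6.16 log2 (SE 0.11), from 12.34 to 6.18, and Esrrb by 5.93 log2 (SE 0.73). Tcl1, Tbx3 and the nuclear receptor gene Nr5a2 were at least 88.9-fold, 65.7-fold and 43.9-fold lower. Klf4 fell by 2.71 log2 (SE 0.22), and all 12 naive genes were lower (median −4.39 log2, adjusted p 9.8e-09; adjusted p = 0.038 with an estimated correlation). The growth factor genes Fgf5 and Fgf8 were at least 45.9-fold and 10-fold higher, Wnt8a at least 5.03-fold, and Pou3f1 rose by 3.76 log2 (SE 0.21). Of 12 post-implantation genes, 9 were higher and 0 lower (adjusted p 0.00021; adjusted p = 0.28 with an estimated correlation). Sox2 fell by 3.31 log2 (SE 0.15), against 0.48 log2 (SE 0.12, adjusted p 0.008) for Pou5f1 and 0.33 log2 (SE 0.09, adjusted p 0.012) for Nanog; the core list had 1 higher and 6 lower of 10 and was not called (adjusted p 0.058). Without EpiLC array 1 neither Pou5f1 (adjusted p 0.057) nor Nanog (adjusted p 0.092) was called, and without 2i array 2 Nanog was not (adjusted p 0.062).

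Epithelial genes rose in 8 of 10 with none lower (median 1.77 log2, adjusted p 0.00021; adjusted p = 0.19 with an estimated correlation). The keratin gene Krt8 rose by 4.12 log2 (SE 0.30), its partner Krt18 by at least 27.5-fold and the tight junction gene Cldn6 by 2.35 log2 (SE 0.10). Imprinted genes were 9 higher and 0 lower of 12 (adjusted p 0.004; adjusted p = 0.24 with an estimated correlation), with Grb10 up by 2.93 log2 (SE 0.07), Cdkn1c by 2.19 log2 (SE 0.14) and Snrpn by 1.71 log2 (SE 0.09). Stress genes were 8 higher and 2 lower of 11 (adjusted p 0.034; adjusted p = 0.28 with an estimated correlation), with the AP-1 genes Fosb up by 3.52 log2 (SE 0.27) and Jun by 1.69 log2 (SE 0.14), and Atf3 by 4.39 log2 (SE 0.14). LIF targets were 1 higher and 6 lower of 9 (adjusted p 0.037; adjusted p = 0.24 with an estimated correlation), with Stat3, the LIF signal transducer gene, down by 2.04 log2 (SE 0.11). Oxidative phosphorylation genes were 0 higher and 9 lower of 19 (adjusted p 0.0071; adjusted p = 0.34 with an estimated correlation), with Cox7a1 down by 2.05 log2 (SE 0.19).

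Among the lists not called, ERK targets had 8 higher and 3 lower of 14 (adjusted p 0.068), with Dusp4 up by 2.66 log2 (SE 0.09), Dusp6 by 2.06 log2 (SE 0.17) and Spred1 by 1.55 log2 (SE 0.07). Germline genes had 0 higher and 6 lower of 7, with the transposon silencing gene Tex19.1 down by 4.50 log2 (SE 0.86), and DNA methylation genes 2 higher and 3 lower of 5, with Dnmt3b up by 1.37 log2 (SE 0.06) and Dnmt3l down by 5.04 log2 (SE 0.90). Trophoblast genes had 3 higher and 1 lower of 7 (4 and 1 alone), with Gata3 at least 4.42-fold higher and Tfap2c down by 4.69 log2 (SE 0.09), and Nodal targets 2 higher and 2 lower of 6, with Lefty2 down by 5.11 log2 (SE 0.49). Fibroblast genes had 2 higher and 6 lower of 15, with Col1a1 down by 4.54 log2 (SE 0.82); the list's mean level was 7.27 and 7.28 on the EpiLC arrays. Neural (−0.23 and 0.32) and proliferation genes (−0.08 and 0.03) had medians and means of opposite sign, and the cholesterol median was 0.16 log2 but −0.09 with median scaling.

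The largest rises among all genes were those of the sulfotransferase gene Chst1 (at least 97.1-fold), the protease inhibitor gene Slpi (at least 87.1-fold) and the carbonic anhydrase gene Car4 (at least 38.5-fold). The largest falls, beside the naive genes, were those of the keratin gene Krt42 (at least 62-fold), Notum (at least 47.2-fold) and Lrrc34 (6.53 log2, SE 0.26). EpiLCs had 5769 called genes, 2880 higher and 2889 lower, with 1225 and 939 at least 2-fold. With median scaling the split was 2377 higher and 3664 lower, and the median change of all genes was −0.11 log2 here, −0.17 log2 between EpiSCs and 2i cells and −0.22 log2 between MEFs and the pluripotent groups.

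EpiSCs, against the same 2i cells, lost the same naive genes and gained streak genes besides post-implantation and epithelial genes (n = 2 per group). Dppa3 and Tbx3 were at least 99.7-fold and 69.2-fold lower, and Klf4 fell by 4.23 log2 (SE 0.22). Esrrb fell by 5.54 log2 (SE 0.73) and the chromatin factor gene Dppa4 by 5.52 log2 (SE 1.21), but their EpiSC arrays lay apart, with standard deviations of 2.24 and 3.72, and Dppa4 was not called with only the groups compared. All 12 naive genes were lower (median −4.27 log2, adjusted p 3.8e-07; adjusted p = 0.066 with an estimated correlation). Post-implantation genes were 9 higher and 0 lower of 12 (adjusted p 0.00042; adjusted p = 0.25 with an estimated correlation), with Otx2 up by 4.06 log2 (SE 0.15), Fgf5 at least 45.3-fold and Fgf15 at least 17.8-fold. Streak genes were 8 higher and 0 lower of 9 (median 1.39 log2, adjusted p 0.0047; adjusted p = 0.2 with an estimated correlation), with Fgf8 at least 49.6-fold, the homeobox gene Lhx1 at least 3.07-fold, Wnt3 at least 2.98-fold and the forkhead gene Foxa2 at least 2.64-fold higher. Epithelial genes were 8 higher and 0 lower of 10 (median 2.28 log2, adjusted p 0.0013; adjusted p = 0.2 with an estimated correlation), with Krt8 up by 5.47 log2 (SE 0.30) and Esrp1 by 3.20 log2 (SE 0.13). Sox2 fell by 3.87 log2 (SE 0.15), while Pou5f1 (0.13 log2, SE 0.12, adjusted p 0.37) and Nanog (0.04 log2, SE 0.09, adjusted p 0.75) were not called. With median scaling Nanog fell by 0.37 log2 (adjusted p 0.0068). The EpiSC arrays also lay apart for Foxa2 (standard deviation 1.03), Krt8 (0.80), Fgf15 (0.76) and Klf4 (0.65).

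Among the lists not called in EpiSCs, extraembryonic endoderm genes had 7 higher and 1 lower of 14, with Dab2 up by 4.13 log2 (SE 0.20) and Gata6 at least 3.68-fold, and ERK targets 7 higher and 1 lower of 14, with Dusp6 up by 2.38 log2 (SE 0.17). Imprinted genes had 8 higher and 3 lower of 12, with Mest at least 43.7-fold higher, and LIF targets 1 higher and 5 lower of 9, with the STAT3 feedback gene Socs3 down by 2.59 log2 (SE 0.09). The Y-linked gene Eif2s3y was at least 64.4-fold and Kdm5d at least 2.36-fold higher; neither was detected in 2i cells. Uty, also Y-linked, was detected on all 14 arrays and was 0.54 log2 (SE 0.10) higher in EpiSCs. The two-cell-like gene Zscan4c was at least 2.59-fold higher (standard deviation 0.89 in EpiSCs). The DNA methylation median was 0.03 log2 but −0.29 with median scaling, against a mean of −0.43; Dnmt3b rose by 1.53 log2 (SE 0.06). The largest rises included Chst1 (at least 106-fold, standard deviation 0.98 in EpiSCs), Car4 (at least 75.2-fold), the X-linked gene Xlr4a (7.05 log2, SE 0.19) and Car14 (6.66 log2, SE 0.22). In all, 6948 genes were called, 3397 higher and 3551 lower, with 1596 and 1302 at least 2-fold.

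Many genes moved alike in EpiLCs and EpiSCs against 2i: 1939 were higher and 1965 lower in both, where independent lists would share 933 and 979. The changes correlated at 0.725 across genes, which are not independent. Part of this excess may come from the shared 2i arrays. With a different 2i array for each comparison, added after seeing the data and leaving 1 control array per comparison, 1662 and 1577 genes were higher and lower in both (independent lists 718 and 706) or, the other way round, 1615 and 1541 (independent lists 713 and 699). The correlation across genes was then 0.713 or 0.709 and the covariance 0.926 or 0.923. In 20 simulations with no change in either group, the shared arrays gave a correlation of 0.497 and a covariance of 0.016, against a covariance of 0.935 in the data. They gave 0 genes higher in both, but simulations without changes yield few calls. That 0 therefore cannot show how far shared arrays raise the overlap where many genes are called. In opposite directions went 562 genes, where independent lists would give 1912, and 357 or 381 with a different 2i array for each comparison (independent lists 1426 or 1413).

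**Figure D3:**
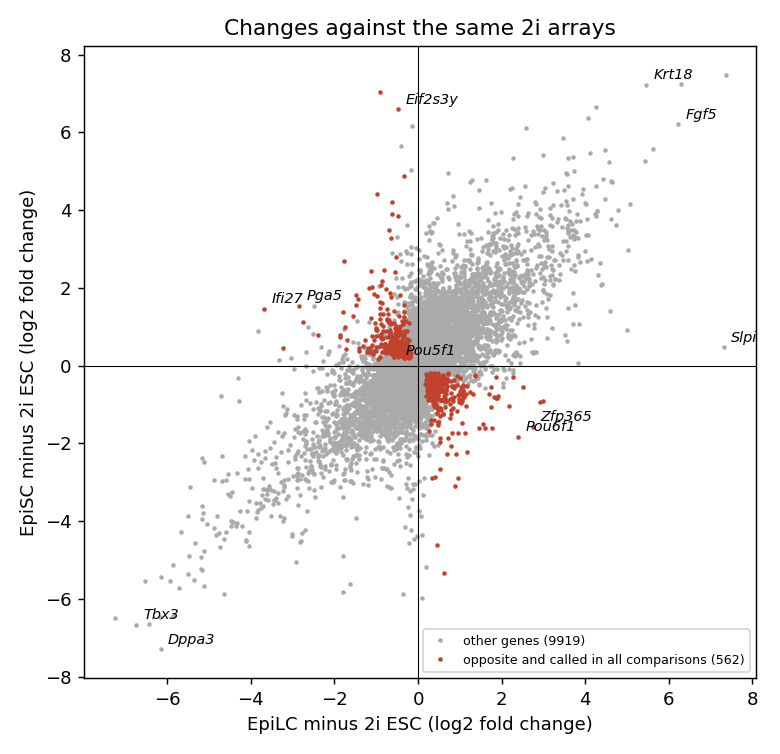
Change against 2i cells (log2) in EpiLCs and in EpiSCs for 10481 genes; 562 genes called in opposite directions and between EpiSCs and EpiLCs are marked. Across genes the changes correlated at 0.725.

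EpiSCs, directly against EpiLCs, differed in single streak, endoderm, Nodal pathway and stress genes, and none of the lists was called (n = 2 per group). The organizer gene Gsc rose by 3.19 log2 (SE 0.31, detected on 1 of 2 EpiLC arrays), Fgf8 by 2.30 log2 (SE 0.21), and Lhx1 and Foxa2 were at least 3.21-fold and 2.77-fold higher; streak genes had 7 higher and 1 lower of 9 (adjusted p 0.097). The endoderm genes Gata6, Sox17 and Pdgfra were at least 3.85-fold, 3.07-fold and 4.06-fold higher, with 9 higher and 1 lower of 14 (adjusted p 0.1). Pdgfra is also a MEF gene here, at 12.41 in MEFs, and its EpiSC arrays, of which array 2 had the higher fibroblast level, had a standard deviation of 1.6. Lefty2 rose by 2.64 log2 (SE 0.49), Lefty1 by 1.79 log2 (SE 0.08) and the Nodal coreceptor gene Tdgf1 by 2.43 log2 (SE 0.25), with Nodal targets 4 higher and 1 lower of 6 (adjusted p 0.11). Otx2 rose by 2.61 log2 (SE 0.15), with post-implantation genes 6 higher and 1 lower of 12, or 7 and 1 alone (adjusted p 0.11). Fosb fell by 2.74 log2 (SE 0.27) and Atf3 by 2.30 log2 (SE 0.14), with stress genes 2 higher and 7 lower of 11 (adjusted p 0.11). Pou5f1 was higher by 0.61 log2 (SE 0.12, adjusted p 0.0021) and Nanog by 0.37 log2 (SE 0.09, adjusted p 0.0072), and Sox2 lower by 0.57 log2 (SE 0.15, adjusted p 0.01). The calls of Nanog and Sox2 were lost without EpiLC array 1, and that of Sox2 also without EpiSC array 1 or background correction. Median scaling ended that of Nanog, and with only the groups compared Nanog, Sox2, Pdgfra and Lefty2 were not called. The EpiSC arrays also lay apart for Lefty2 (standard deviation 1.5), Foxa2 (1.03), Sox17 (0.91), Fosb (0.74), Gsc (0.72) and Tdgf1 (0.70).

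Trophoblast genes were 4 higher and 1 lower of 7, with the keratin gene Krt7 up by 3.30 log2 (SE 0.34) and Tfap2c by 2.37 log2 (SE 0.09). Imprinted genes went both ways (3 and 3 of 12): Mest was at least 45.8-fold higher, and Grb10 fell by 3.85 log2 (SE 0.07) and Cdkn1c by 3.22 log2 (SE 0.14); the list median was 0.06 log2 but −0.02 with median scaling, as that of oxidative phosphorylation genes moved from 0.13 to −0.03. The core median was −0.12 log2, but 0.03 without background correction, and the test pointed up; the naive median (0.11) and mean (−0.12) also differed in sign. Proliferation genes had 1 higher and 5 lower of 10, with the replication genes Mcm2 and Rrm2 down by 0.97 log2 (SE 0.08) and 0.96 log2 (SE 0.14). Cholesterol genes had 2 higher and 6 lower of 11 (2 and 7 alone) and mesenchymal regulators 0 and 4 of 7 (0 and 5 alone). The largest rises included Xlr4a (at least 199-fold), Eif2s3y (at least 67.4-fold), the redox enzyme gene Glrx (5.22 log2, SE 0.10), the interferon-response gene Ifi27 (5.15 log2, SE 0.17, detected on 1 of 2 EpiLC arrays) and the actin regulator gene Cap1 (4.83 log2, SE 0.10). The largest falls included Slpi (6.84 log2, SE 0.28), the neural factor gene Olig1 (6.06 log2, SE 0.30), both detected on 1 of 2 EpiSC arrays, the mitotic kinase gene Plk1 (5.97 log2, SE 0.08) and the signalosome gene Cops8 (5.37 log2, SE 0.26). The standard deviation of the EpiSC arrays was 0.82 for Krt7, 0.87 for Olig1, 0.74 for Slpi and 0.78 for Cops8. Plk1 and Cops8 each rested on a single detected probe, and the cells of this comparison were of different lines.

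EpiSCs and EpiLCs differed in 5912 genes, 2922 higher and 2990 lower, with 943 and 779 at least 2-fold. The fibroblast and feeder list had a mean level of 6.85 on EpiSC array 1 and 8.98 on array 2, so that its members were mostly not called (1 higher and 0 lower of 15). Fitted with only the groups compared, 3407 genes were called.

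The single-reporter ESCs, against the mean of the serum gates of the double-reporter line, had higher levels of fibroblast genes, called as a list, and lower levels of cholesterol synthesis genes, also called (n = 2 and 4 arrays). Neither list was called with an estimated correlation (adjusted p = 0.9 and 0.85). The matrix genes Lum, Lox, Col1a1 and Dcn rose by 4.58 log2 (SE 0.18), 4.09 log2 (SE 0.74), 3.80 log2 (SE 0.71) and 2.75 log2 (SE 0.71). The matrix Gla gene Mgp rose by 9.55 log2 (SE 0.36, detected on 1 of 4 double-reporter arrays), to 15.02 against 10.15 in MEFs. The acute phase gene Lcn2, the selectin gene Selp and the protease inhibitor gene Serpina3n were at least 81.6-fold, 66.7-fold and 20.3-fold higher, with Lcn2 at 12.02 against 4.68 in MEFs. The fibroblast list's mean level was 10.91 and 10.97 on these arrays, against 8.88 to 8.93 on the double-reporter serum arrays and 12.73 and 12.80 on the MEF arrays. Fibroblast genes had 10 higher and 1 lower of 15 (adjusted p 0.017; adjusted p = 0.9 with an estimated correlation). With them moved the mesenchymal genes Twist1, up by 2.47 log2 (SE 0.35), and Vim, by 2.24 log2 (SE 0.38), with 5 higher and 1 lower of 7. The basement membrane genes Col4a2 and Col4a1 rose by 4.0 log2 (SE 0.45) and 3.61 log2 (SE 0.21), with extraembryonic endoderm genes 8 higher and 1 lower of 14.

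**Figure D4:**
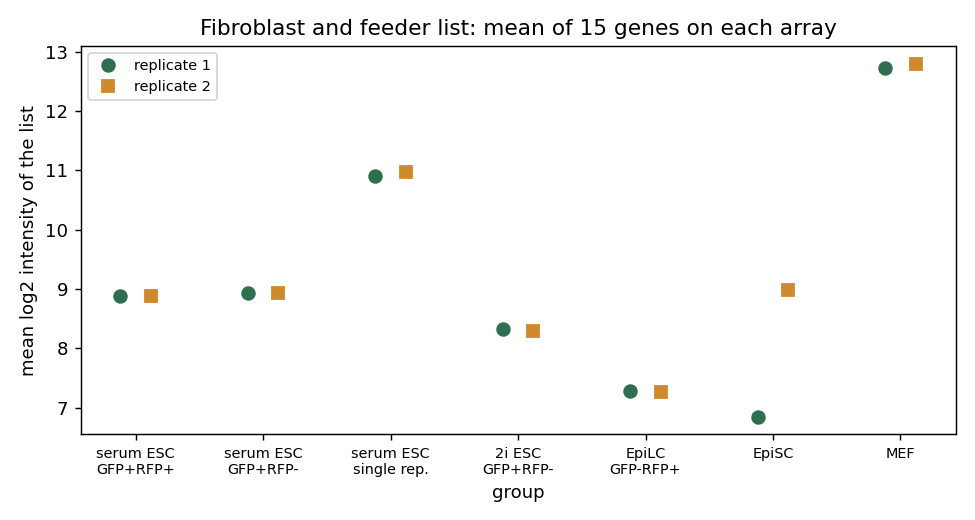
Mean level (log2 signal) of the fibroblast and feeder list on each array. It was 10.91 and 10.97 on the single-reporter arrays, 6.85 and 8.98 on the EpiSC arrays and 12.73 and 12.80 on the MEF arrays.

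Post-implantation genes were 2 higher and 8 lower of 12 in the single-reporter ESCs and not called as a list (adjusted p 0.16), with Pou3f1 down by 3.28 log2 (SE 0.18), Otx2 by 1.61 log2 (SE 0.13) and Dnmt3b by 1.28 log2 (SE 0.06). Core genes were 1 higher and 6 lower of 10: the RNA-binding gene Lin28a fell by 2.81 log2 (SE 0.11), Tdgf1 by 2.44 log2 (SE 0.22), Nanog by 0.70 log2 (SE 0.08) and Pou5f1 by 0.33 log2 (SE 0.11, adjusted p 0.021), while Sox2 was not called (−0.12 log2, SE 0.13, adjusted p 0.45). Naive genes went both ways (5 and 3 of 12), with Nr5a2 up by 1.23 log2 (SE 0.36) and Tbx3 by 0.98 log2 (SE 0.15). The calls of Nr5a2 and Pou5f1 were lost without either single-reporter array, and that of Pou5f1 also without RFP-negative serum array 2. Cholesterol genes were 1 higher and 9 lower of 11 (median −0.50 log2, adjusted p 0.021; adjusted p = 0.85 with an estimated correlation), with Msmo1 down by 4.03 log2 (SE 0.08) and Insig1 by 1.87 log2 (SE 0.10). Oxidative phosphorylation genes were 3 higher and 7 lower of 19 (3 and 6 alone), with Atp5a1 down by 2.69 log2 (SE 0.11), and epithelial genes 0 and 6 of 10, with the cadherin gene Cdh1 down by 1.30 log2 (SE 0.12). Among the largest falls, those of Msmo1, the GTPase gene Gpn2 (3.93 log2, SE 0.09) and the ribosomal gene Rps3a1 (3.75 log2, SE 0.10) each rested on a single detected probe in a comparison of different lines, as did the smaller fall of Atp5a1. Medians and means differed in sign for ERK targets (−0.29 and 0.21), stress genes (−0.34 and 0.18) and streak genes (−0.05 and 0.24; the streak median was 0.06 with median scaling). The glycolysis median moved from 0.05 to −0.04. Of 6616 called genes, 3285 were higher and 3331 lower, with 1098 and 1206 at least 2-fold.

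MEFs, against the mean of the 6 pluripotent groups, had lower levels of all 10 core pluripotency genes and higher levels of all fibroblast genes and mesenchymal regulators (n = 2 and 12 arrays). Pou5f1, the zinc finger gene Sall4 and Dppa5a were at least 163-fold, 189-fold and 330-fold lower, Sox2 at least 5.58-fold, and Nanog fell by 6.97 log2 (SE 0.07), to 6.60, where it was still detected on both MEF arrays. Col1a1 rose by 6.10 log2 (SE 0.62), the proteoglycan gene Ogn by 7.74 log2 (SE 0.08, detected on 4 of 12 pluripotent arrays), Col3a1 by 6.12 log2 (SE 0.12, detected on 8 of 12), the growth factor gene Ptn by 6.49 log2 (SE 0.09) and Vim by 2.90 log2 (SE 0.34). All 15 fibroblast genes were higher (adjusted p 0.00023; adjusted p = 0.27 with an estimated correlation), as were all 7 mesenchymal regulators (0.01; adjusted p = 0.27 with an estimated correlation), and 9 of 11 cholesterol genes with none lower (0.024; adjusted p = 0.27 with an estimated correlation). All 10 core genes (0.00023; adjusted p = 0.11 with an estimated correlation), all 10 proliferation genes (0.00023; adjusted p = 0.19 with an estimated correlation) and all 5 DNA methylation genes (0.0063; adjusted p = 0.24 with an estimated correlation) were lower, the replication gene Mcm5 by 4.01 log2 (SE 0.06) and Dnmt3b by 6.89 log2 (SE 0.05).

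Naive genes were 2 higher and 10 lower of 12 (adjusted p 0.0063; adjusted p = 0.19 with an estimated correlation), with Esrrb at least 140-fold lower, and post-implantation genes 1 and 10 of 12 (0.0049; adjusted p = 0.27 with an estimated correlation). Glycolysis genes were 1 higher and 12 lower of 13 (0.0029; adjusted p = 0.11 with an estimated correlation), with the glucose transporter gene Slc2a3 down by 6.25 log2 (SE 0.07), and epithelial genes 0 and 9 of 10 (0.0036; adjusted p = 0.19 with an estimated correlation), with Cdh1 at least 60.8-fold lower. Also lower were Wnt targets (1 and 7 of 8, 0.024; adjusted p = 0.19 with an estimated correlation), with Axin2 at least 12.7-fold, and Nodal targets (0 and 5 of 6, 0.01; adjusted p = 0.25 with an estimated correlation), with Lefty2 at least 56.7-fold. BMP targets (4 higher and 0 lower of 7, 0.047; adjusted p = 0.22 with an estimated correlation) and imprinted genes (9 and 2 of 12, 0.041; adjusted p = 0.25 with an estimated correlation) were higher, with Id4 up by 3.89 log2 (SE 0.15, detected on 10 of 12 pluripotent arrays) and Dlk1 by 4.14 log2 (SE 0.13, detected on 9 of 12). Eif2s3y rose by 5.15 log2 (SE 0.11, detected on 8 of 12). ERK targets went both ways (5 and 5 of 14), with a median of 0.09 log2, −0.12 with median scaling, and a mean of −0.11. In all 8799 genes were called, 4178 higher and 4621 lower, with 2333 and 2321 at least 2-fold.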

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

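All tests in this part were chosen after seeing the results they examine. The predictions for fibroblast RNA, for MEF levels and for ESC RNA were also written after their values were seen, and those for second probes and for the spread outside fibroblast genes before.

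Some genes moved in opposite directions in EpiLCs and EpiSCs against the same 2i cells and also differed directly between both. There were 562 such genes, 291 of them higher in EpiLCs than in 2i and 271 higher in EpiSCs. Of these, 27 moved at least 2-fold in each direction, and a script picked the 5 with the largest direct difference among those 27. Between EpiSCs and EpiLCs, Ifi27 differed by 5.15 log2 (−3.68 in EpiLCs and 1.47 in EpiSCs against 2i), Prxl2a by 4.47 log2 (−1.77 and 2.70) and the pepsinogen gene Pga5 by 4.38 log2 (−2.84 and 1.55). The zinc finger gene Zfp365 differed by −4.33 log2 (2.76 in EpiLCs and −1.57 in EpiSCs) and the POU factor gene Pou6f1 by −4.23 log2 (2.40 and −1.83). Ifi27 had a second detected probe with a difference of 5.38 log2, while Prxl2a, Pga5, Zfp365 and Pou6f1 had none, so for these 4 a single probe carries the value. The 2 groups come from different lines, and the sample titles give a sort gate for EpiLCs but not for EpiSCs. Median scanner signals also differed (148.6 and 142.6 on the EpiLC arrays, 313.5 and 316.8 on the EpiSC arrays). A true difference between these cells, a line difference and an effect of sorting or of the arrays remain open for all 5. A probe effect remains open for the 4 with a single probe.

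Fibroblast genes were higher in the single-reporter ESCs than in the double-reporter ESCs. Fibroblast RNA, for example of feeder cells, would raise most genes that MEFs express far above ESCs, and 85.9% of these (61 of 71) were called higher, at a median of 8.6% of their MEF signal (quartiles 3.6% to 15.4%). This is consistent with fibroblast RNA on these arrays. Of 100 genes at least 8-fold higher in these cells, however, 33 lay more than 2-fold above their MEF level, among them Mgp (15.02, against 10.15 in MEFs), Lcn2 (12.02 against 4.68) and Saa3 (13.61 against 5.72), which fibroblasts like those on the MEF arrays could not give. Feeder cells in another state and a true difference of the ESC line were not tested and remain open. A sort gate is given for the double-reporter ESCs only, so sorting and line cannot be told apart here.

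The EpiSC arrays lay further apart than the arrays of other groups, with a standard deviation of the replicate difference of 0.576 log2 against 0.166 to 0.218. Fibroblast RNA on array 2 would raise MEF genes there, and 90.9% of them (130 of 143) were higher on array 2, by a median of 1.52 log2, which is consistent with it. Outside genes 2-fold higher in MEFs the standard deviation was still 0.45 over 8072 genes, so fibroblast RNA leaves much of the spread unexplained, and of 591 genes more than 1 log2 apart 314 were MEF genes. RNA of ESCs like the double-reporter line on array 1 was tested in 3 versions, all set after the values were seen: 72.9% of ESC genes (86 of 118) were higher on array 1 and 12.7% (15 of 118) lay more than 2-fold below the level of the smallest share that the most shifted genes allow (4.2%), both undecided. In the version kept, 30.8% (8 of 26) lay below it, such as Dppa3 at 5.09 against 7.53 required, which argues against such ESCs as the only source; ESCs of another kind and a true culture difference were not tested.

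Several of the largest changes between lines rested on a single probe. If sequence differences between lines weakened single probes, second probes would disagree more often between lines than within the double-reporter line. They disagreed for 16.7% of genes between lines (31 of 186) and 6.2% within the line (15 of 241; Fisher's exact p 8e-04). The excess came mainly from the single-reporter ESCs (24 of 126, exact p 0.00028; falls 19 of 47, rises 5 of 79), which is consistent with it there, while EpiSCs against EpiLCs (7 of 60, exact p 0.17) leave it open, although there too falls (6 of 27) disagreed more often than rises (1 of 33), against 4 of 41 and 4 of 88 falls within the line. Splice forms and probe quality were not tested, and for falls without a second probe, such as those of Msmo1, Gpn2 and Rps3a1 in the single-reporter ESCs and of Plk1 and Cops8 in EpiSCs, a probe effect stays open.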

How the results depend on the processing

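The alternatives were set before the data were examined, except the fits without the EpiSC arrays, without the single-reporter arrays, without genes at least 2-fold higher in MEFs, and with a different 2i array for EpiLCs and EpiSCs, which were added after seeing the data. List tests in the added fits are not reported.

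The number of genes called between the serum gates depended most on the processing, as only 13 were called. It was 19 without background correction or with the authors' values, 13 with median scaling, 9 without the detection filter, 14 with the stricter detection limit or an intensity trend, 10 with all probes or without the MEF arrays, and 4 at 2-fold or more. With only the serum arrays in the fit it was 0, and without the EpiSC arrays 53 (4 higher and 49 lower), because the EpiSC replicates widen the spread shared by all groups. Without the single-reporter arrays it was 9, and without genes higher in MEFs 10. With 1 array left out it ranged from 1 (RFP-negative array 1) to 45 (EpiSC array 1), and a group left with 1 array is then assumed to vary like the others.

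The other counts held within narrower limits. Requiring at least 2-fold left 1067 of 4163 genes between 2i and RFP-negative serum cells, 1108 of 4258 between RFP-positive serum and 2i cells, 2164 of 5769 for EpiLCs and 2898 of 6948 for EpiSCs against 2i, 1722 of 5912 for EpiSCs against EpiLCs, 2304 of 6616 for the single-reporter ESCs and 4654 of 8799 for MEFs. With only the groups compared, the count of EpiSCs against EpiLCs dropped to 3407. With 1 array left out, the counts ranged from 2929 to 5251 for 2i against RFP-negative serum cells, 3063 to 5305 for RFP-positive serum against 2i cells, 4827 to 6614 and 6119 to 7434 for EpiLCs and EpiSCs against 2i, 4852 to 6462 for EpiSCs against EpiLCs, 5612 to 7409 for the single-reporter ESCs and 8187 to 9229 for MEFs. In each of these the highest count came without an EpiSC array. Without genes higher in MEFs, 4858 genes were called in the single-reporter ESCs, 1849 higher and 3009 lower, against 3285 and 3331 of all genes.

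Replicate numbers were also fitted as a replicate block, which gave 9 genes between the serum gates, 4113 and 4227 between each gate and 2i, 5723 and 6924 for EpiLCs and EpiSCs against 2i, 5857 for EpiSCs against EpiLCs, 6596 for the single-reporter ESCs and 8788 for MEFs. The numbers showed little sign of pairing samples: over 21 pairs of groups the correlation of replicate differences across genes was −0.03 to 0.09. Of the 14 arrays, however, 10 correlated best on average with arrays of their own number, so a weak shared effect stays open. A chip block was not run because the column names give no chips.

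Scaling changed signs near 0. Nanog did not differ between EpiSCs and 2i cells (0.04 log2), but with median scaling it was lower there (−0.37 log2, adjusted p 0.0068). Median scaling called fewer genes higher in RFP-positive serum cells, EpiLCs and EpiSCs against 2i (1793, 2377 and 2856). The cause was not tested.

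Of 233 named gene values, 22 lost their call in some alternative, 11 of them between the serum gates. The requirement of at least 2-fold and the fit without genes higher in MEFs were not counted here. The 2-fold requirement would also end every named call of a smaller change, such as that of Pou5f1 between EpiSCs and EpiLCs (0.61 log2). AA467197 and Tfap2c lost theirs with the replicate block (adjusted p 0.06 and 0.1), all probes or no detection filter, and Nanos3 with an intensity trend and robust eBayes (0.09). Dnmt3l, lower in 2i than in RFP-negative serum cells but not called (0.067), gained a call without background correction (0.012), with the authors' values (0.014), with only the groups compared (0.00014) and without either EpiSC array. Pou5f1 gained a call between RFP-positive serum and 2i cells with only the groups compared (0.046). Without background correction or with the authors' values the call of Adh7 was lost (−0.38 and −0.41 log2), as that of Sox2 between EpiSCs and EpiLCs (−0.21 and −0.23 log2). With only the groups compared, Dppa4 in EpiSCs (adjusted p 0.07), and Pdgfra (0.074) and Lefty2 (0.062) between EpiSCs and EpiLCs, were not called. Changes of dim genes depend on the background: those near background shrink without its correction.

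The list calls depended on the correlation between genes: 41 were made over the 8 comparisons with the preset value and 1, the fall of naive genes in EpiLCs, with an estimated correlation. With 1 array left out they ranged from 41 to 64 (without EpiSC array 2). The median change between the serum gates of genes higher in EpiLCs was −0.035 to −0.019 log2 and that of genes lower in EpiLCs −0.008 to 0.003 log2 with 1 array left out. For the sets from EpiSCs it was −0.033 (camera p 0.057) and 0.015 log2 (camera p 0.74).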

Other observations

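The interferon and germ cell members tested below were chosen after the first genes of each kind were seen, with the predictions written before the new members were computed. In serum, the gate defined by the proximal-enhancer reporter marked few expression differences. Pou5f1 (13.77 and 13.64) and the naive and post-implantation lists (medians −0.08 and 0.18 log2) were not called. Genes higher in EpiLCs than in 2i had a median of −0.03 log2 between the gates. Dppa3 was lower and called without background correction (−0.56 log2), and 2 naive genes were lower when adjusted over the list alone. With 2 arrays per gate, 41% of changes of 0.5 log2 were found in simulations with 200 changed genes. That many changes ease the adjustment over genes, so this share likely overstates what could be found with 13 calls. In the main fit the smallest called change was 0.62 log2 (Tfap2c), so small shifts of many genes stay open. Of the 13 called genes 7 were also lower in EpiLCs than in 2i, 3 were higher and 3 were not called. Of all 10481 genes, 2889 were lower and 2880 higher there. The count was made after the genes were seen, so a link of the reporter with a part of that change stays open. The called genes fell in RFP-positive cells, and among them were Rhox6, Rhox9, Nanos3 and Tfap2c, which germ cells express.

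EpiLCs and EpiSCs shared the loss of naive genes and of Sox2 and the gain of Fgf5, Krt8 and Krt18. EpiSCs had higher Gsc, Fgf8, Lefty1 and Tdgf1, although neither the streak nor the Nodal list was called between them, while EpiLCs had higher Fosb, Atf3 and Grb10. Over all pluripotent groups Nanog stayed between 12.74 and 14.06 and Pou5f1 between 13.06 and 13.77, so that naive and primed states differed less in these than in their partner Sox2.

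Interferon-response genes were lower in 2i than in serum cells of the same gate. After 8 members, among them Usp18, Ifit3 and Oasl2, were seen, 25 further members of the family were listed before their values were computed: 20 were lower and 0 higher, with a median of −1.09 log2 (camera p 6.3e-08, and 0.00053 with an estimated correlation), with Mx2 at −2.42 log2 (SE 0.14) and Irf7 at −1.90 log2 (SE 0.29) as examples picked afterwards. Fibroblast RNA on the serum arrays could in principle carry such genes. Of the lower members, though, 64.3% (18 of 28) had serum levels called above those of MEFs. That argues against fibroblasts like those on the MEF arrays as the main source. Fibroblasts in another state were not tested and remain open. In the single-reporter ESCs, where fibroblast genes were higher, 13 of the 25 further members were higher and 9 lower than in double-reporter serum cells (median 0.39 log2, camera p 0.37). The family was higher in EpiSCs than in EpiLCs (median 0.90 log2, 17 higher and 1 lower). However, it was also lower in EpiLCs than in 2i (median −0.43 log2, 4 higher and 12 lower, camera p 0.017, adjusted p 0.034). With an estimated correlation this camera p was 0.032 before adjustment over the comparisons, and an adjusted value was not computed. The family was not called in EpiSCs against 2i (median 0.54 log2, camera p 0.25). A hypothesis is that serum, or what it contains, keeps a low interferon response active in ESCs; ESCs in serum-free medium without inhibitors, and serum with a JAK inhibitor, would separate it from an effect of the inhibitors.

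A hypothesis from the Rhox and Nanos3 falls is that RFP-negative serum cells contain a fraction with germ cell genes. It would lower other germ cell genes in RFP-positive cells, but 8 members chosen after these were seen had a median of −0.06 log2 with 0 called (camera p 0.11), which leaves it open. The 7 tested genes of the germline list had a median of 0.08 log2, from −0.88 (Rhox5) to 0.30 (Ddx4). Rhox9 and Rhox6 were at 10.45 and 8.69 in 2i cells, against 10.04 and 8.34 in RFP-negative serum cells. In EpiLCs they were at 4.73 and 4.81, so high levels were not particular to RFP-negative serum cells. Rhox5, a member of the germline list, was lower but not called (−0.88 log2, SE 0.65). It was at 10.03 ± 0.16 in RFP-positive and 10.91 ± 0.11 in RFP-negative serum cells. Its EpiSC arrays had a standard deviation of 1.98, which widens the SE because all groups share 1 spread. Rhox12 was not called either (0.08 log2, SE 0.16) and is named after its value was seen. Sorted fractions with more replicates, or single-cell measurement of Rhox6, Rhox9 and Nanos3 with both reporters, would test the hypothesis.

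The low fibroblast signal in EpiSC array 1 and the higher one in array 2 invite a test by feeder depletion before RNA is taken. The Y-linked gene Eif2s3y was at 11.68 and 12.02 in EpiSCs, 12.12 and 12.14 in MEFs and 7.42 and 7.48 in the single-reporter ESCs. It was 6.14 to 6.51 on the double-reporter serum arrays and not detected in 2i cells and EpiLCs, which are of the same line. The fibroblast list's mean level was 8.88 to 8.93 on those serum arrays, 8.32 and 8.30 in 2i cells and 7.28 and 7.27 in EpiLCs. Whether fibroblast RNA carried the weak Eif2s3y signal in serum was not tested. Kdm5d, also Y-linked, was detected only in EpiSCs and MEFs, whereas Uty was detected on every array, at 7.06 and 7.03 in EpiSCs and at 6.63 and 6.38 in 2i cells. MEF RNA at a median of 8.6% of the MEF signal may account for part or all of the raised Eif2s3y signal in the single-reporter ESCs, which was not tested. Genotyping the lines would settle their sex.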
